A study of Homo sapiens with 6 samples.

How the data were processed

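The samples were 6 arrays of MDA-MB-231 RNA, 1 for each of PBS, LPS, IL1b, TNFa, IL6 and TGFb, after 24 h of treatment. Groups were taken from the treatment given in the labels. Per the labels' protocols, total RNA was extracted with TRIzol, reverse transcribed and labelled with Cy3. The labels describe an Arraystar long non-coding RNA array in NimbleGen format, scanned on an Axon GenePix scanner whose model number rises by 1 from sample to sample. The deposited files, in contrast, are 1-colour Agilent Feature Extraction output, with 62738 spots per array and Agilent control spots. The files were followed, and the conflict is not resolved by the sources used here.

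The deposited intensity values per spot are the processed signals of the scanner software, already corrected for background, per the file headers. The deposited flags of each spot say whether it was an outlier or well above background. The authors also deposited a series table of log2 values. The submitters' processing notes name RMA, with its version not given in the sources used here. Set against the scanner values, each column of that table equalled the quantile-normalized log2 intensity to a median absolute difference of at most 0.000624 over probes well above background, with a largest single difference of 1.2 on the PBS array, so its scale and direction are known and it is not centred on genes. Its column medians were 5.07 with PBS, LPS and IL6 and 5.08 with IL1b, TNFa and TGFb.

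Spots flagged as outliers were left out, repeat spots of a probe were averaged on the log2 scale, and control spots were left out. Of 60639 target probes, 43 had no unflagged spot on some array and 60596 were used. Quantile normalization in limma 3.58.1 (R 4.3.3) of log2 intensity was the main setting. The choice was not fixed before the data were examined. It follows the RMA named by the submitters and the form of their table, and it was made after the counts of 2-fold differences had been seen under both quantile scaling and scaling to the 75th percentile, which is the usual setting for such files and is given as an alternative. No background step was run, since the signals were already corrected and the mean and background columns were not used here.

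A probe was counted when the brighter array lay above its median (the floor) and the absolute log2 difference was at least 1. It was called set apart when it also lay at least 1 the same way from the median of the other 4 treated arrays. With 1 array per group there was no test. The array to array spread was described by the robust SD over all 15 pairs. Gene lists and probe classes were described by the percentile of their median among 10000 random lists matched in 20 bins of mean intensity. Named probes were the 12 largest each way per treatment among those set apart, up to 4 of each list or class, the 5 each way with the largest smallest difference over all treatments, and the 8 each way over IL1b and TNFa. The text gives part of the selected probes, mainly those measured on both arrays, and an item was left out as not reported here. For the set-apart and shared ranks, only differences measured on both arrays (for all treatments, on all 6) were ordered, since values at the floor have no order; this narrowing was made after the files were seen. The rule asked for a gene symbol, which was read as the name the file gives. Where a probe was not well above background on 1 array, the fold was taken against the higher of 2 values on that array. These were its own value and the lowest value among probes well above background. Such a fold is not a strict lower bound. On the PBS array that lowest value was 4.54, while LUST at 6.65 and uc.137- at 6.47 were not well above background. No fold is given where both arrays were below background.

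Of 166 probes carrying a RefSeq mRNA accession, 160 were matched to a current symbol in the RefSeq table of assembly GRCh38.p14. Another 6 transcripts were matched to a symbol by name. No genome build is named for the array, so no positions are given. No table was used that gives genes for the 59231 probes with only a number, and the protein-coding and non-coding classes could not be counted apart.

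The alternatives were the series table, cyclic loess (span 0.7, 3 iterations), no floor, a floor at the 75th percentile, 1.5-fold and 3-fold thresholds, the median of the other 5 arrays as control and 1 value per gene symbol. Scaling to the 75th percentile in 2 forms, detection in place of the floor and a difference from each of the other 5 arrays were added after the data were seen. The counting rule was checked on simulated arrays of 60596 probes drawn around the PBS array, with 200 changed probes. At a log2 change of 3, 100% were called in each direction, and at 1.5, 94% of the higher and 88% of the lower, with 58 unchanged probes called. The simulated noise had an SD of 0.221 per array, from LPS and IL1b as the closest pair (spread 0.31), while comparisons with PBS had spreads of 0.86 to 1.23, so the simulation gives no rate of false calls for them. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for counts.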

Results

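Transcript levels were measured in MDA-MB-231 cells, a human breast cancer cell line, after 24 h with PBS as the control or with 1 of 5 stimuli. The stimuli were LPS (bacterial lipopolysaccharide, a ligand of TLR4), the inflammatory cytokines IL1b and TNFa, IL6 (which signals through STAT3) and TGFb (which signals through SMAD proteins). The experiment was set up to find long non-coding RNAs that respond to inflammatory stimuli. Each group had 1 array, hybridized with Cy3-labelled material, so no difference below has a replicate check and no p-value is given. The number of arrays limits the precision of every value. Differences are log2 values on the quantile-normalized scale, treated minus PBS, unless a fold is given.

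Of 60639 target probes, 60596 were used and 19077 were well above background on all 6 arrays. The files pair 1365 of the probes with a name, and the other 59231 carry only a probe number and stay unnamed. The named probes covered 20 mRNAs spotted repeatedly, exons, introns and non-coding transcripts of the HOX clusters (developmental transcription factor genes), ultraconserved genomic regions (uc. probes, each with a strand sign) and 25 other transcripts. Detection differed between arrays. The share of probes well above background was 33.2% with PBS, 40.7% with LPS, 49.0% with IL1b, 43.5% with TNFa, 68.4% with IL6 and 56.3% with TGFb. Negative control spots, which have no human target, were well above background in 0.5% of cases with PBS, 1.83% with LPS, 2.33% with IL1b, 1.83% with TNFa, 12.8% with IL6 and 11.2% with TGFb.

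**Figure D1:**
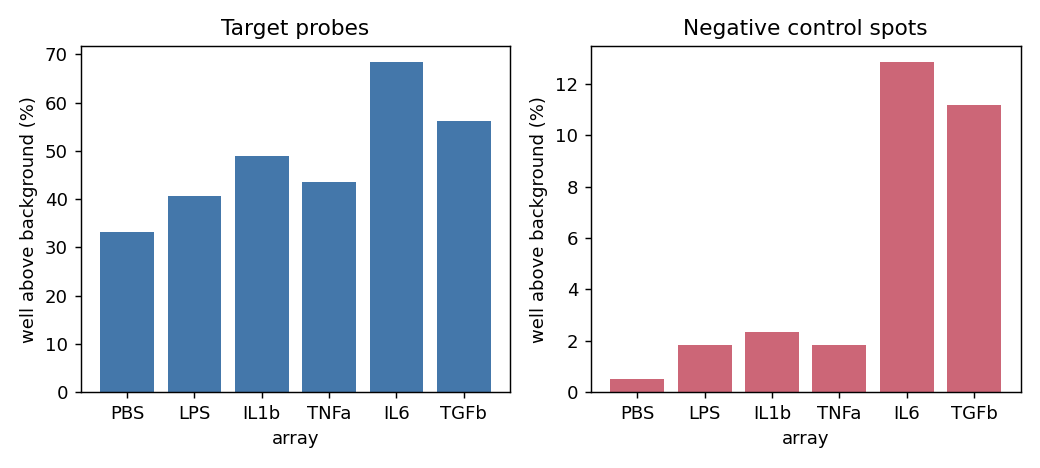
Bars give the percentage of target probes (left) and of negative control spots (right) that were well above background on each of the 6 arrays. The IL6 and TGFb arrays had the highest shares in both panels, 68.4% and 56.3% of target probes and 12.8% and 11.2% of negative control spots.

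The spread between arrays was compared over all 15 pairs. The robust SD of log2 differences was 0.31 between LPS and IL1b, 0.32 between IL1b and TNFa, 0.40 between LPS and TNFa and 0.49 between IL6 and TGFb. It lay between 0.86 and 1.23 for every pair with PBS, and between 1.07 and 1.28 for IL6 or TGFb against LPS, IL1b or TNFa. Among probes well above background on all 6 arrays, 141 differed at least 2-fold between LPS and IL1b, while 2287 differed between PBS and LPS and 5432 between PBS and TGFb. Every comparison with PBS shares the single PBS array, and a probe was therefore also asked to stand at least 2-fold off the median of the other 4 treated arrays. A probe that differs alike on a pair of treated arrays can pass in both, so set apart does not mean particular to a single treatment.

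**Figure D2:**
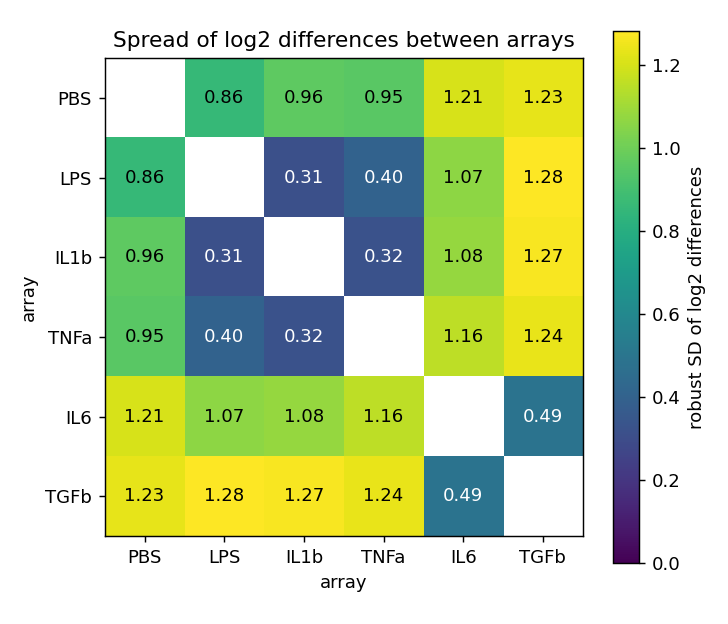
The colour and the number in each cell give the robust SD of log2 differences between 2 arrays, over probes above the intensity floor. LPS, IL1b and TNFa lie close together (0.31 to 0.40), IL6 and TGFb lie at 0.49 from each other, and PBS lies at 0.86 or more from each treated array.

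Some named transcripts were higher on several treated arrays than on the PBS array. TncRNA, the NEAT1 transcript that scaffolds nuclear paraspeckles, was 2.94-fold higher with LPS, 2.68-fold with IL1b, 2.56-fold with TNFa, 2.54-fold with IL6 and 1.79-fold with TGFb. PRMT1, an arginine methyltransferase, was the only mRNA with repeat spots past 2-fold. It was higher by 1.09 ± 0.027 with LPS, 1.33 ± 0.028 with IL1b and 1.36 ± 0.028 with TNFa, where the error is the standard error over repeat spots within the arrays and covers spot noise alone. The probe named p53mRNA was 2.26-fold higher with LPS and 2.17-fold with IL1b. Its difference was 0.57 with TNFa, 0.84 with IL6 and 0.16 with TGFb. Across the 5 treatments, 1280 probes were at least 2-fold higher than PBS in every one and 1406 were lower in every one, 324 and 325 of them well above background on all 6 arrays. Where passing the floor on any of the treated arrays was enough, the PBS array lay at least 2-fold below each of the other 5 in 2605 probes, beside 1406 in which it lay above each. Of named probes measured on all 6 arrays, uc.419- and uc.418- were higher with every stimulus, by at least 1.19 and 1.05. Among those lower with every stimulus were nc-HOXB4-175, nc-HOXB9-184, nc-HOXB8-183 and uc.155-. The probe nc-HOXB9-184 differed by -1.53 with LPS, -1.93 with IL1b, -1.94 with TNFa, -2.11 with IL6 and -2.30 with TGFb. A probe off PBS the same way with all 5 stimuli is, by construction, one in which the PBS array stood off the other 5, and against the median of the other 5 arrays several of these differences turned sign. On that footing TncRNA lay at 0.21 with LPS, 0.08 with IL1b, 0.01 with TNFa, -0.01 with IL6 and -0.51 with TGFb. Of 39 named differences of at least 2-fold in probes with a gene symbol, 12 were still at least 2-fold and 4 turned sign when all probes of the symbol were averaged, which takes in probes at background. Among exon probes well above background on all 6 arrays, 4 HOX genes had at least 2, and in 0 of these genes did the probes differ from PBS in both directions with IL6.

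**Figure D3:**
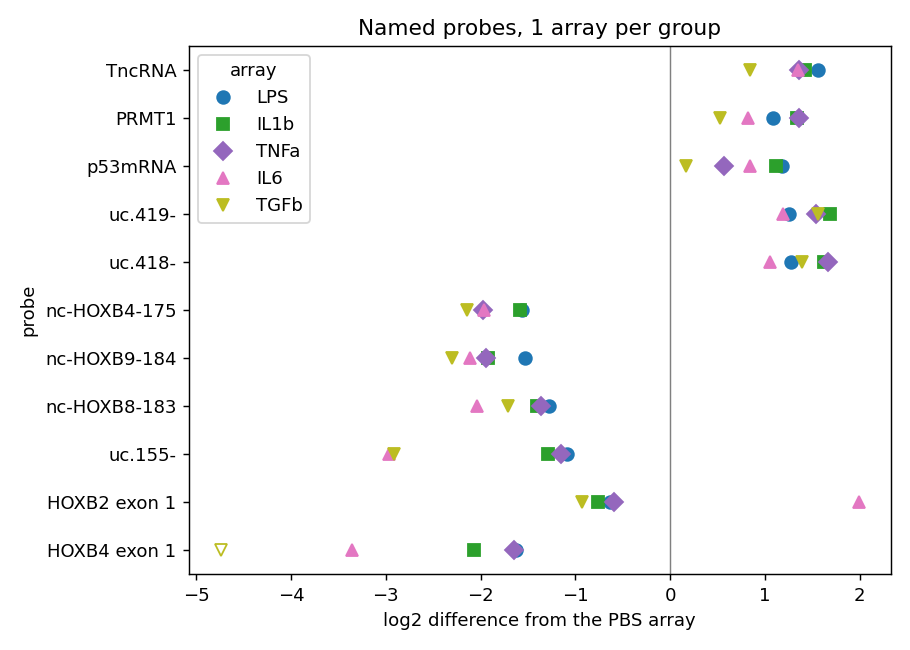
Points give the log2 difference of each treated array from the PBS array for 11 named probes, with 1 marker per treatment; open markers are probes not well above background on an array compared. TncRNA lay at 0.84 to 1.56 and nc-HOXB9-184 at -2.30 to -1.53 over the 5 treatments, while HOXB2 exon 1 stood at 1.99 with IL6 alone.

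LPS was compared with PBS to ask which transcripts differ after exposure to endotoxin. Measured on both arrays and set apart from the other treatments were nc-HOXB9-197 (2.31-fold higher), uc.212+ (2.26-fold), uc.291+ (2.10-fold) and uc.246+ (2.06-fold). Lower were nc-HOXA13-100 (3.48-fold) and nc-HOXC6-240 (2.27-fold). The non-coding HOX cluster probes as a class were lower, with a median of -0.59 over 144 members above the floor, at percentile 0 among 10000 random lists of like intensity. In the same class, 12 probes well above background on both arrays were at least 2-fold lower and 1 was higher. With the floor alone, 25 were lower, 6 of them set apart. Over all probes, 5164 were at least 2-fold higher and 3650 at least 2-fold lower than with PBS, out of 33609 above the floor. Of these, 1088 and 682 were also set apart. With both arrays well above background the counts were 1342 and 1020, with 25 and 48 set apart. Scaling to the 75th percentile of probes well above background on all 6 arrays turned the balance, to 3769 higher and 5572 lower.

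IL1b, which acts through the interleukin-1 receptor, was compared with PBS in the same way. Named probes set apart and measured on both arrays were lower, namely nc-HOXC6-240 (2.47-fold) and nc-HOXD11-5 (2.06-fold). HOXD13 exon 1 was 5.00-fold lower and CARIntergenic10 3.42-fold lower, and neither was set apart. With IL1b, HOXD13 exon 1 lay at 5.176, beside 5.168 as the lowest value among probes well above background on that array. It was well above background on 4 arrays and CARIntergenic10 on 3. The mean over all probes of HOXD13 differed by -0.21, and CARIntergenic10 lay 1.29 above the median of the other 5 arrays. HOXC11 exon 2, not well above background with PBS, stood 6.41-fold above the lowest PBS value well above background, which is not a strict lower bound. The mean over all probes of HOXC11 differed by 1.06. Non-coding HOX cluster probes had a median of -0.72, at percentile 0 among random lists, and exons of HOX genes a median of -0.59, at percentile 0.03. Counts over all probes were 5999 higher and 4352 lower, with 818 and 433 set apart. Restricted to probes well above background on both arrays, 1872 were higher and 1909 lower, 15 and 118 of them set apart. Under the 75th percentile of probes well above background on all 6 arrays, 5045 were higher and 5795 lower.

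TNFa, a cytokine that activates NF-kB, was compared with PBS in the same way. Among named probes, nc-HOXB9-197 was 2.61-fold higher and set apart. Intron 2 of NM_153715, a transcript of the HOX clusters, was 2.41-fold lower. CARIntergenic10 with PBS stood 4.12-fold above the lowest value well above background with TNFa, where its own value was not well above background. With TNFa, uc.89+ stood 20.2-fold above the lowest such value with PBS, where its own was not well above background. Neither fold is a strict lower bound. HOX cluster non-coding probes had a median of -0.56 (percentile 0) and HOX exons a median of -0.46 (percentile 0.19). Over all probes, 6122 were higher and 4649 lower than with PBS, with 1235 and 672 set apart. Under the 75th percentile of probes well above background on all 6 arrays, 5318 were higher and 5394 lower. Among probes measured on both arrays, 1777 were higher and 1750 lower, 69 and 68 of them set apart.

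The differences of IL1b and TNFa from PBS were set side by side because both cytokines act through NF-kB. Higher with both were uc.418- (3.09-fold and 3.17-fold), uc.419- (3.21-fold and 2.91-fold), uc.75- (2.59-fold and 2.79-fold), TncRNA (2.68-fold and 2.56-fold), PRMT1 (2.52-fold and 2.56-fold), uc.268- (2.92-fold and 2.44-fold), uc.174+ and uc.285+. Lower with both were nc-HOXB9-184, HOXB4 exon 1 (4.20-fold and 3.14-fold), nc-HOXB4-175, HOXC4 exon 2 (2.69-fold and 2.92-fold), nc-HOXB8-183, nc-HOXB4-172, uc.338+ and nc-HOXA4-65. The means over all probes of HOXB4 differed by -0.51 with IL1b and -0.16 with TNFa, and those of HOXC4 by -0.27 and -0.36. Against the median of the other 5 arrays, the sign turned for nc-HOXB4-175 (0.38) and nc-HOXB9-184 (0.013) with IL1b, and for HOXB4 exon 1 (0.42), nc-HOXA4-65 (0.20) and nc-HOXB8-183 (0.046) with TNFa, and TncRNA lay at 0.08 and 0.01. In all, 4392 probes were higher and 3024 lower with both, against 803.2 and 621.2 in independent lists of the same sizes. The sharing was not particular to this pair, since LPS and IL1b shared 3691 higher and 2647 lower, against 638.3 and 490.8. Of those of IL1b and TNFa, 128 higher and 101 lower were set apart from the other treatments in each of the 2, 0 and 9 of them well above background on all 6 arrays. Part of the excess over independent lists can come from the shared PBS array.

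IL6 was compared with PBS in the same way. The largest named differences set apart and measured on both arrays were higher for nc-HOXC6-248 (7.31-fold), uc.427+ (5.14-fold), nc-HOXC11-115 (4.78-fold), uc.204- (4.23-fold) and nc-HOXC9-139 (4.15-fold). All of these except uc.204- were also set apart and higher with TGFb. HOXB2 exon 1 was 3.97-fold higher with IL6 and stood above each of the other 5 arrays by at least 1.99, but the mean over all probes of HOXB2 differed from PBS by -0.0021. HOXA11 exon 1 (2.98-fold), nc-HOXA13-100 (3.31-fold), uc.10-, uc.293-, uc.341- and uc.345- were also higher. Lower were HOXB4 exon 1 (10.2-fold), uc.85+ (9.38-fold), uc.91+ (8.57-fold), nc-HOXD10-14 (8.27-fold), uc.155- (7.80-fold) and HOXD9 exon 1 (7.45-fold), followed by uc.339+, uc.443-, nc-HOXB9-189, uc.18+, HOXB1 exon 1 and uc.90-. The means over all probes of a gene differed from PBS with IL6 by -0.06 for HOXB4, -1.12 for HOXD9, -1.47 for HOXB1 and 0.51 for HOXA11. Several of these probes lay at normalized log2 values under 5 with IL6. The lowest value among probes well above background was 3.26 with IL6, beside 4.48 to 5.94 on the other 5 arrays. With IL6, nc-HOXD10-14 (3.63), uc.443- (4.06), HOXD9 exon 1 (4.13), uc.339+ (4.27) and nc-HOXB9-189 (4.28) lay under all of those limits. Such values would not have passed as measured on another array, which bears on these folds and on counts of lower probes measured on both arrays. On that array 12.8% of negative control spots were well above background, though these spots were not placed on the normalized scale. Over all probes, 7358 were higher and 7528 lower, with 4399 and 3348 set apart. With both arrays well above background, the counts were 1926 and 4078, and under the 75th percentile of probes well above background on all 6 arrays they were 11109 and 5546. The split of higher and lower probes with IL6 thus had no settled direction.

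TGFb was compared with PBS in the same way, on named probes set apart and measured on both arrays. Among those higher were nc-HOXC6-248 (6.32-fold), nc-HOXC11-115 (4.07-fold), nc-HOXC9-139 (3.91-fold), uc.10- (3.89-fold), uc.345- (3.66-fold) and uc.427+ (3.43-fold), then uc.88-, nc-HOXD11-5, uc.341-, uc.355+ and uc.18-. Of these, nc-HOXC6-248, nc-HOXC11-115, nc-HOXC9-139, uc.10-, uc.345-, uc.427+ and uc.341- were also among the set-apart probes named with IL6. Lower were uc.308- (13.3-fold), uc.163- (12.7-fold), uc.91+ (11.7-fold), uc.117+ (9.12-fold), uc.30+ (8.69-fold), nc-HOXC6-252 (7.75-fold) and uc.155- (7.53-fold), then uc.18+, uc.325-, nc-HOXC4-263, nc-HOXC8-146 and HOXC10 exon 1 (mean over all probes of HOXC10 -0.99). With TGFb, uc.308-, uc.163-, uc.91+, uc.117+, uc.155-, uc.18+ and nc-HOXC4-263 lay at normalized log2 values of 4.59 to 4.98. The lowest value among probes well above background on that array was 4.48, and 11.2% of its negative control spots were well above background. Of the lower probes, uc.91+, uc.155- and uc.18+ were also named as set apart with IL6. HOXB3 exon 2 and HOXB3 exon 4 lay below each of the other 5 arrays, by -1.22 and -1.39, and HOXC8 exon 1 lay above each by 1.16; these 3 were chosen after their values were seen. The means over all probes differed from PBS by 0.08 for HOXB3 and -0.42 for HOXC8, against the sign of these exons. Over all probes, 7688 were higher and 7658 lower, with 4410 and 4176 set apart. With both arrays well above background, the counts were 1955 and 3690, and under the 75th percentile of probes well above background on all 6 arrays they were 12115 and 5533.

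IL6 and TGFb shared 4617 higher and 5880 lower probes, against 1118.6 and 1732.6 in independent lists, and 342 probes went opposite ways. With comparisons that share no array, IL6 and TGFb correlated across probes at a median r of 0.39 over 6 choices of controls, with a range of 0.38 to 0.46. For IL1b and TNFa it was 0.12 (0.10 to 0.17), for LPS and IL1b 0.07 (-0.10 to 0.19) and for LPS and IL6 -0.15 (-0.46 to -0.03). Probes are not independent replicates. The other treated arrays serve as controls here, so the values of these pairs are not separate. The highest r of IL6 and TGFb (0.46) is the lowest of LPS and IL6 (-0.46) with its sign turned. The values describe which arrays group together and do not tell a response from arrays processed apart. With PBS shared, r was 0.82 for IL6 and TGFb, 0.83 for IL1b and TNFa and 0.81 for LPS and IL1b, beside 0.50 for simulated unchanged arrays. The covariances were 1.67, 1.18 and 1.08, beside 0.049 in the simulation, whose noise was that of the closest pair of arrays. A noisier PBS array would add to all of them.

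Among the 24 gene lists fixed before the data were examined, 9 of 536 symbols were found among the named probes, so that inflammatory cytokines, NF-kB targets, SMAD targets and receptors of the stimuli were not analysed here. The housekeeping list had 4 members above the floor, with ACTB within 0.12 of PBS on every array, but at -0.61 with IL1b under cyclic loess and -1.68 with IL6 under scaling to the 75th percentile of all probes, and PGK1 lower by -0.70 with IL6 and -0.54 with TGFb. Its medians ran from 0.07 with TGFb to 0.15 with TNFa, at percentiles of 60.9 to 71.2, and its mean had the opposite sign with IL6 (-0.03) and TGFb (-0.04). The ribosomal protein list had 3 members, with RPS18 between 0.34 and 0.43 and RPLP1 between 0.03 and 0.15, and list medians at percentiles of 64.2 to 84.1. Scaling to the 75th percentile of all probes put RPS18 at -1.07 with IL6 and RPLP1 at -1.37. The hypoxia and glycolysis list had 1 member, PGK1, and the list of known long non-coding RNAs had 1 above the floor, TncRNA. Of 18 repeat-spot mRNAs well above background on all 6 arrays, 17 stayed within 2-fold of PBS on every treated array under quantile scaling, but not ACTB under scaling to the 75th percentile.

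Classes of named probes were defined after the names and values were seen, so their percentiles only describe these arrays. The lean of non-coding HOX cluster probes to lower values was not particular to them. Of unnamed probes numbered ASHG19A3L and measured on both arrays, 53 were lower and 13 higher with LPS, 109 and 14 with IL1b, and 91 and 11 with TNFa. Those numbered ASHG19A3H leaned lower as well, with 10 and 0, 27 and 1, and 21 and 1. The ASHG19A3A probes, 55293 of the 60596 used, leaned the other way, with 938 and 1316, 1731 and 1847, and 1605 and 1753. That lean was slight with IL1b (9.15% lower and 9.76% higher) and TNFa (8.58% and 9.37%). Of lower non-coding HOX cluster probes, 5 of 36 with IL1b and 2 of 25 with TNFa were set apart. Non-coding HOX cluster probes above the floor were at percentile 0 with LPS, IL1b and TNFa. These percentiles all rest on the same PBS array and are not separate results. The class had medians of -0.09 with IL6 (percentile 3.96) and -0.07 with TGFb (percentile 6.83), which turned to 0.20 and 0.29 with scaling to the 75th percentile of probes well above background on all 6 arrays. Measured on both arrays, the class had medians of -0.34 with IL6 (percentile 3.15) and -0.07 with TGFb (percentile 41.6). Ultraconserved region probes measured on both arrays had a median of -0.36 with LPS (percentile 7.41), -0.60 with IL1b (percentile 0.19) and -0.49 with TNFa (percentile 1.23), and of 0.05 with IL6 (percentile 99.9) and 0.06 with TGFb (percentile 98.9), while over probes above the floor these medians were 0.19 and 0.13, at percentiles of 63.1 and 38.7, and the IL6 median turned to -0.05 with scaling to the 75th percentile of all probes and the TGFb median to -0.0034 with cyclic loess. HOX exons measured on both arrays had medians of -0.51 with LPS, -0.78 with IL1b, -0.75 with TNFa, -0.63 with IL6 and -0.76 with TGFb, at percentiles of 4.32, 0.2, 0.16, 12.6 and 1.01. Over HOX exons above the floor the IL6 median was 0.11 and turned to -0.26 with cyclic loess and -0.18 with scaling to the 75th percentile of all probes, and the TGFb median was -0.10 and turned to 0.42 with scaling to the 75th percentile of probes well above background on all 6 arrays. The 9 HOX introns measured on both arrays had medians of -0.64 with LPS, -0.80 with IL1b, -0.64 with TNFa, 0.49 with IL6 and 0.48 with TGFb, at percentiles of 3.07, 2.12, 6.63, 96.6 and 94.9.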

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

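Of the tests in this part, the one of the PBS array as the odd one out and the one of control spots were chosen after the results were seen. The tests on the brightest 25% of probes were written before their spreads were seen, but after those over all probes.

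Named probes well above background on all 6 arrays that stood at least 2-fold above PBS with 1 stimulus and at least 2-fold below it with another were noted, and the differences were not tested. For nc-HOXB9-197 the values were 1.38 with TNFa and -1.85 with TGFb. The probe uc.204- stood at 2.08 with IL6 and -1.07 with TGFb. Opposite values of 1.04 with LPS and -1.02 with TNFa were found for uc.246+. For uc.293- they were 1.79 with IL6 and -1.63 with TGFb, for nc-HOXC6-240 1.10 with IL6 and -1.31 with IL1b, and for nc-HOXA13-100 1.73 with IL6 and -2.30 with TGFb.

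The share of negative control spots well above background was higher on each treated array than on the PBS array. Negative control spots were well above background in 1.83% of cases with LPS, 2.33% with IL1b, 1.83% with TNFa, 12.8% with IL6 and 11.2% with TGFb, against 0.5% with PBS.

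The PBS array stood apart from LPS, IL1b and TNFa, which lay close together. Lower sensitivity of the dim PBS array is argued against as the whole cause, since in the brightest 25% of probes the smallest spread against PBS was still 2.37 times the largest among these 3 arrays (bootstrap interval over probes 2.27 to 2.48, 4770 probes). That interval covers the sampling of probes and not variation between arrays of a group, for which there was no replicate. For the position of the spots, only shifts between blocks of 500 neighbouring rows are argued against, and only for LPS minus PBS. These blocks held 0.802% of its variance, beside 0.637% with rows shuffled. Block medians cannot show a pattern within blocks, and the IL1b and TNFa arrays were not examined in this way. The PBS array may be the odd one out of all 6: of the probes off PBS with LPS, IL1b and TNFa alike, 94.4% differed from it the same way with IL6 and 92.2% with TGFb, and the lower of the IL6 and TGFb medians was 0.733 times that in LPS, IL1b and TNFa. A response shared by all stimuli predicts the same and stays open, untested.

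The IL6 and TGFb arrays stood apart from the other 4, with 25.7% to 31.5% of probes well above background on all 6 arrays at least 2-fold off LPS, IL1b or TNFa, against 0.739% to 1.57% among those 3. Non-specific signal at low intensity may account for part of this, since in the brightest 25% the smallest spread against LPS, IL1b and TNFa was 1.155 times the largest among those 3 (interval over probes alone 1.11 to 1.21), and 1.60 times for TGFb alone, but the spread of TGFb against LPS was 0.50 there, beside at most 0.24 among the 3. Control spots without a human target were well above background in 15.615% of cases with TGFb and 24.8% with IL6. The share was at most 5.83% on the other 4 arrays. E1A and ERCC probes are among them, with no word in the sources used here on added RNA. Negative control spots alone gave 11.2% with TGFb and 12.8% with IL6, against at most 2.33%. The 3xSLv1 control spots gave 3.25% with TGFb but only 0.32% with IL6, beside 0.32% with PBS, 0.97% with IL1b and 1.30% with LPS and TNFa. Labelling, hybridization or scanning done apart may give the higher shares. The position of the spots cannot be told apart from this, at 7.987% of the variance of IL6 minus LPS in blocks of rows, beside 0.122% with rows shuffled and between the bounds set for it. A response to IL6 and TGFb is confounded with these, as each had 1 array.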

How the results depend on the processing

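No paired analysis was possible because each group had 1 array. Scaling to the 75th percentile, detection in place of the floor, the difference from each of the other 5 arrays and every alternative for the set-apart counts were chosen after the data were seen. The background alternative was not run, since the mean and background columns were not used here. The set-apart counts were not rerun with the median of the other 5 arrays as control or with 1 value per gene symbol. For lists, the mean over a gene's probes is the same computation as 1 value per gene symbol. The series table gave counts within 1.5 times the main ones for all 5 treatments. The cause of the changes was not tested, except that a lower threshold or floor, by construction, lets more probes in and a stricter one fewer.

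Counts against PBS that moved by over 1.5 times were, with no floor, higher 8394 (LPS), 9289 (IL1b), 9348 (TNFa). With a floor at the 75th percentile, higher 1796 (LPS), 2549 (IL1b), 2458 (TNFa), 2545 (IL6), 2575 (TGFb) and lower 935 (LPS), 1504 (IL1b), 1471 (TNFa), 2824 (IL6), 2885 (TGFb). With a 1.5-fold threshold, higher 8285 (LPS), 9032 (IL1b), 11100 (IL6), 11569 (TGFb) and lower 8975 (LPS), 10566 (IL1b), 10205 (TNFa). With a 3-fold threshold, higher 3079 (LPS), 3603 (IL1b), 3858 (TNFa), 4593 (IL6), 4980 (TGFb) and lower 1696 (LPS), 1569 (IL1b), 1811 (TNFa), 4731 (IL6). With the median of the other 5 arrays as control, higher 1915 (LPS), 1792 (IL1b), 2306 (TNFa) and lower 1222 (LPS), 1147 (IL1b), 1296 (TNFa), 4246 (IL6). With both arrays well above background, higher 1342 (LPS), 1872 (IL1b), 1777 (TNFa), 1926 (IL6), 1955 (TGFb) and lower 1020 (LPS), 1909 (IL1b), 1750 (TNFa), 4078 (IL6), 3690 (TGFb). With a 2-fold difference from each of the other 5 arrays, higher 632 (LPS), 316 (IL1b), 602 (TNFa), 613 (IL6), 1175 (TGFb) and lower 188 (LPS), 46 (IL1b), 111 (TNFa), 443 (IL6), 772 (TGFb). With scaling to the 75th percentile of probes well above background on all 6, lower 5572 (LPS) and higher 11109 (IL6), 12115 (TGFb). With the brighter array well above background, lower 1503 (LPS), 2148 (IL1b), 2216 (TNFa), 4199 (IL6), 4279 (TGFb).

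Counts set apart that moved were, with no floor, higher 1844 (LPS), 1541 (IL1b), 2172 (TNFa). With a floor at the 75th percentile, higher 103 (LPS), 87 (IL1b), 192 (TNFa), 1766 (IL6), 1441 (TGFb) and lower 44 (LPS), 86 (IL1b), 45 (TNFa), 958 (IL6), 1467 (TGFb). With a 1.5-fold threshold, higher 2298 (LPS), 2997 (IL1b), 2991 (TNFa), 7083 (IL6), 7320 (TGFb) and lower 2403 (LPS), 2747 (IL1b), 2835 (TNFa), 6074 (IL6), 6619 (TGFb). With a 3-fold threshold, higher 680 (LPS), 392 (IL1b), 702 (TNFa), 2008 (IL6), 2219 (TGFb) and lower 238 (LPS), 64 (IL1b), 126 (TNFa), 1044 (IL6), 1896 (TGFb). With scaling to the 75th percentile of probes well above background on all 6, higher 585 (LPS), 345 (IL1b), 766 (TNFa), 7602 (IL6), 8394 (TGFb) and lower 1697 (LPS), 1309 (IL1b), 1314 (TNFa), 1248 (IL6), 1736 (TGFb). With the brighter array well above background, higher 631 (LPS) and lower 142 (LPS), 155 (IL1b), 156 (TNFa), 1795 (IL6), 2409 (TGFb). With both arrays well above background, higher 25 (LPS), 15 (IL1b), 69 (TNFa), 1280 (IL6), 1034 (TGFb) and lower 48 (LPS), 118 (IL1b), 68 (TNFa), 1742 (IL6), 1949 (TGFb).

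The median shift of HOX cluster exons, LPS minus PBS, was 0.0005 with the median of the other 5 arrays as control. The median shift of cytosolic ribosomal proteins, IL6 minus PBS, was -1.07 with scaling to the 75th percentile of all probes. The median shift of cytosolic ribosomal proteins, TGFb minus PBS, was -0.95 with scaling to the 75th percentile of all probes. The correlation of IL1b and TNFa was 0.19 with cyclic loess. The correlation of IL6 and TGFb was 0.38 with no floor.

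Named differences of at least 2-fold whose sign turned were, with 1 value per gene symbol, HOXB2 exon 1 -0.0021 (IL6), HOXC8 exon 1 -0.42 (TGFb), HOXB3 exon 2 0.085 (TGFb), HOXB3 exon 4 0.085 (TGFb). With the median of the other 5 arrays as control, uc.419- -0.29 (LPS), uc.419- -0.35 (IL6), uc.418- -0.11 (LPS), uc.418- -0.33 (IL6), nc-HOXB4-175 0.40 (LPS), nc-HOXB4-175 0.38 (IL1b), nc-HOXB9-184 0.40 (LPS), nc-HOXB9-184 0.013 (IL1b), nc-HOXB8-183 0.13 (LPS), nc-HOXB8-183 0.046 (TNFa), uc.155- 0.20 (LPS), uc.155- 0.14 (TNFa), HOXB4 exon 1 0.42 (TNFa), nc-HOXA4-65 0.20 (TNFa), CARIntergenic10 1.28 (LPS), CARIntergenic10 1.29 (IL1b), ENST00000519624 0.010 (TNFa), TncRNA -0.011 (IL6).

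With scaling to the 75th percentile of probes well above background on all 6 arrays, the median difference from PBS over all probes was -0.85 with LPS, -0.80 with IL1b, -0.74 with TNFa, -0.17 with IL6 and -0.09 with TGFb, beside -0.09, -0.20, -0.08, -0.01 and -0.14 under the main setting. The repeat-spot mRNAs with IL1b had a median of 0.32, at the edge of the random lists, and of -0.0074 with cyclic loess, -0.33 with scaling to the 75th percentile of probes well above background on all 6 arrays and -0.25 with scaling to the 75th percentile of all probes. Under the last of these, the same mRNAs moved from 0.15 to -1.02 with IL6 and from 0.04 to -1.06 with TGFb. A list was called turned only where its main median lay outside the random lists, a rule set after the data were seen. Of 1610 values of named probes under the alternatives, 1432 moved by less than the spread of their comparison with PBS, 156 moved by more and 22 turned sign from a difference of at least 2-fold. That spread was 0.86 with LPS, 1.21 with IL6 and 1.23 with TGFb. With IL6 and TGFb a value could therefore move by over 2-fold and still count among the 1432. Of 183 differences of at least 2-fold, 114 were still at least 2-fold against the median of the other 5 arrays, 174 with scaling to the 75th percentile of all probes and 180 with cyclic loess. Signal over background limits the counts: of the probes higher than PBS, 68.8% to 74.6% were not well above background with PBS. On the treated array itself, 1463 of the higher probes with LPS, 191 with IL1b and 1201 with TNFa were not well above background, and 0 with IL6 and TGFb. Of the lower probes, 72.05% with LPS, 52.9% with IL1b, 62.3% with TNFa, 18.7% with IL6 and 44.8% with TGFb were not well above background on the treated array.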

Other observations

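Of probes without a name, those well above background on all 6 arrays and farthest from each of the other 5 arrays were looked up after the data were seen. ASHG19A3A011673 stood 4.36 (log2) above every other array with TGFb, and ASHG19A3A014218 stood 3.59 above with TNFa. ASHG19A3A044994 lay lower with TGFb by -3.97, and ASHG19A3A036226 with IL6 by -2.81.

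Among ultraconserved region probes, uc.162- stood above each of the other arrays with TGFb by 1.21, at a normalized log2 value of 14.5. The transcript ENST00000519624 was 4.12-fold lower with IL6 and 3.91-fold lower with TGFb than with PBS, and its TNFa value of 2.02-fold lower turned to 0.010 (log2) above the median of the other 5 arrays. The probe mascRNA, the small RNA processed from the MALAT1 locus, lay between -0.35 with TGFb and 0.54 with IL6.

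The following test was chosen after its values had been printed. Probes of 1 HOX gene may follow its transcript: over 9 exon probes of 4 genes well above background on all 6 arrays, the IL6 minus PBS differences of probes of 1 gene correlated at 0.548, with a bootstrap interval over genes of -0.92 to 0.75. With so few genes the data do not decide.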
